A study of Lacticaseibacillus paracasei with 6 samples.

How the data were processed

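Lacticaseibacillus paracasei strain L9, a lactic acid bacterium, had been grown anaerobically at 37 °C in MRS, the standard rich medium for lactobacilli, to mid-exponential phase. RNA was sequenced in 3 samples from MRS with 0.13% oxgall (dried ox bile) and in 3 from MRS without it. Per the labels' protocols, total RNA was isolated with TRIzol, libraries were made with a strand-specific NEBNext kit, and paired-end reads were generated on an Illumina HiSeq. The labels number the samples within each group but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

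The authors' deposited count table held whole-number read counts per gene, not normalized. The authors' deposited FPKM table held counts scaled by gene length and library size. All FPKM values (100%) equalled the count scaled by gene length and by the library's summed counts, within a relative tolerance of 1e-06, so both tables carry the same information. The other deposited table used gave, per the file headers, the authors' log2 fold change and adjusted p-value of each gene for bile against control, with the start, end, strand and length of each gene and its Gene Ontology (GO) terms. Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0 are named in the submitters' processing notes, which give no roles for them. The genome build, the annotation source, the handling of reads that map to several places and the strand setting of the counting are not given in the sources used here. If the counting dropped reads with several equally good positions, genes present in near-identical copies would be listed too low or at 0. The libraries summed to between 3099487 and 4063163 counts.

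The table had 2916 rows on 1 chromosome sequence, with positions counted from 1. Its gene name and product columns were blank in every row, so the files do not pair locus tags with gene names. Genes are therefore given by locus tag, position and deposited GO terms. These terms look assigned by similarity and include some from other kinds of organism, such as autophagy and sporulation, so a term is a label of the gene in the deposited table and not evidence of its function here. A total of 383 rows had 0 counts in all libraries, among them all 15 ribosomal RNA rows (LPL9_r tags).

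Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, edgeR's default filter (minimum count 10) and the quasi-likelihood F-test, bile against control, with no covariate. The filter left 2391 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05, and the standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Values in CPM, counts scaled to a common library size, use TMM factors and are given as mean ± SD of 3 libraries. The same code was tested on simulated counts for this comparison, with 200 of 2391 genes changed. It recovered 71.6% of 1.5-fold changes, 95.5% of 2-fold changes and 100% of 4-fold changes, and 7.77% of its calls were genes left unchanged. The last share is above the threshold of 0.05. In the data a far larger share of genes was called (60.1%), so these rates need not hold there. Counts of pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom between 4.57 and 25.4), so counting depth alone does not set the precision and no library appeared to be present more than once.

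A total of 33 gene list themes and the rule for naming genes were fixed before the data were examined. The lists had been fixed as expressions to be matched to product text. Because that text was blank, 29 themes were mapped by hand to deposited GO terms, after the annotation and the authors' overall number of changed genes had been seen and before any test was run here. The remaining 4 themes (cold, alkaline and universal shock proteins, teichoic acids, bile salt hydrolase, and ribosomal and transfer RNA genes) had no counterpart among the terms. Lists with at least 5 tested genes (27 lists) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, 2-sided, adjusted over the lists. As alternatives, camera was run with an estimated correlation and fry was run as a directional test.

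Named genes were, in each direction, the 8 with the largest log2 fold change among those past the threshold with a mean of at least 50 counts per library, all 3 bile libraries beyond all 3 control libraries, and at least 1 deposited function or process term, which stands in for the product name the rule asked for. To these were added up to 3 such genes for each list called by camera and 1 for each other list. Genes and runs of neighbouring genes outside this rule were chosen after their values were seen, and are said to be where they appear. A run was defined as at least 3 adjacent rows on 1 strand, all past the threshold and changed at least 2-fold in 1 direction, and was compared with 10000 shuffles of the tested genes' changes over their positions. In addition, 624 GO terms with 5 to 150 tested genes were scanned with camera.

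The alternatives were DESeq2 1.42.0, RLE, upper-quartile and total-count scaling, no filter, a filter of at least 10 CPM in 3 libraries, removal of ribosomal and transfer RNA rows, the replicate number as a block, removal of each library in turn, and limma on log2(FPKM + pseudocount) with pseudocounts of 1 and 0.1. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A genome sequence and a functional annotation other than the deposited one were not used here. Results for some genes and regions are not reported here.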

Results

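The transcriptome of L. paracasei L9 growing with bile was compared with that of the same strain growing without it, to describe the response of the bacterium to bile stress. RNA-seq read counts were available for 3 libraries from medium with 0.13% oxgall and 3 control libraries. The bile libraries summed to 4063163, 3099487 and 3750525 counts and the control libraries to 3433338, 3700279 and 3346215 counts. Between 2507 and 2513 genes had at least 1 count in each library, and the 10 most abundant genes took between 12.8% and 14.3% of the counts.

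Most tested transcripts differed between the bile and control libraries, mostly by less than 2-fold. Of 2391 genes tested, 1437 (60.1%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 756 higher and 681 lower with bile. The median size of these changes was 0.62 on the log2 scale. At least 2-fold changes were found for 306 genes, 175 higher and 131 lower, and 4-fold changes for 18 genes that rose and 17 that fell. In the authors' deposited table, 1184 of the 2533 genes with an adjusted p were under 0.05. Of these 1184, 1178 were also called here, all in the same direction.

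The largest increase was in a set of 3 adjacent genes on the plus strand at positions 984352 to 986449, chosen for description after its values were seen. LPL9_0970, which has no deposited GO term, rose 24.4-fold, from 22.4 ± 9.07 CPM in the control to 545 ± 88.8 CPM with bile (SD, n = 3 each; edgeR adjusted p = 1.91e-06). Its neighbour LPL9_0969, also without a term, rose 10.6-fold. The remaining gene, LPL9_0968, carries kinase-binding and cell division terms and was the most abundant of them. It rose 9.92-fold, from 432 ± 102 to 4283 ± 700 CPM.

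Among the genes with function or process terms, the largest rises were in a pair of minus-strand genes at 1653276 to 1655653, which overlap by a few bases. LPL9_1667, with a metal ion binding term, rose 15.6-fold from 8.41 ± 2.09 to 131 ± 49.1 CPM (log2 fold change 3.96 ± 0.31 SE, edgeR adjusted p = 1.67e-05). LPL9_1668, with GTPase and signal-recognition targeting terms, rose 12.5-fold. A pair at 58055 to 61965 on the minus strand also rose. It consists of LPL9_0057, with recombinase and DNA-binding terms (8.23-fold), and LPL9_0056, a gene of 3312 bp with receptor-binding and cell adhesion terms (5.17-fold, reaching 3830 ± 372 CPM). LPL9_0433, with an aspartic endopeptidase term, rose 7.46-fold from a low level of 4.81 ± 2.17 CPM. LPL9_1419, a protein tyrosine phosphatase by its term, rose 5.68-fold, and LPL9_2126, with only a general catalytic term, rose 5.7-fold.

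A run of 13 adjacent minus-strand genes, LPL9_2199 to LPL9_2211 at positions 2216311 to 2226857, fell in every member, by log2 fold changes between -2.95 and -1.67 with SEs of at most 0.16. Of these, 3 carry fatty acid synthesis terms. LPL9_2209 and LPL9_2204 both carry the term for 3-oxoacyl-[acyl-carrier-protein] synthase, the enzyme that elongates the growing fatty acid chain. LPL9_2209 fell 5.13-fold, from 312 ± 19.7 to 60.7 ± 6.4 CPM (SD, n = 3 each; edgeR adjusted p = 7.33e-07), and LPL9_2204 fell 4.96-fold. LPL9_2199, at the end of the run, carries the term for acetyl-CoA carboxylase, which makes the malonyl-CoA building block, and had a log2 fold change of -1.91 ± 0.16 SE. Other members were LPL9_2205 with an oxidoreductase term (5.47-fold lower), LPL9_2201 with a ligase term (4.4-fold lower) and LPL9_2210 with transcription factor and serine peptidase terms (4.7-fold lower). The steepest fall in the run was in LPL9_2206, which has no term (7.72-fold). The run was singled out after its values were seen. In 10000 shuffles of gene positions the longest run had 5 genes (permutation p = 1e-04, the smallest this number of shuffles can give). The shuffles treat neighbouring genes as independent, which genes transcribed together are not. The p-value therefore bears only on whether neighbours changed together, not on bile or on this run in particular.

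Outside that run, the largest decreases were in 2 genes with GTPase terms. LPL9_1342 (1320571 to 1321500, plus strand) fell 8.1-fold, from 144 ± 28.8 to 17.8 ± 5.23 CPM (edgeR adjusted p = 1.47e-05, n = 3 each). LPL9_2680 (2705919 to 2707745, plus strand) fell 6.9-fold, from 1141 ± 61.7 to 165 ± 49.9 CPM. LPL9_3017, a sugar phosphotransferase system gene by its terms, fell 4.84-fold with a wider spread between libraries (293 ± 154 against 1418 ± 494 CPM, log2 fold change -2.27 ± 0.39 SE).

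**Figure D1:**
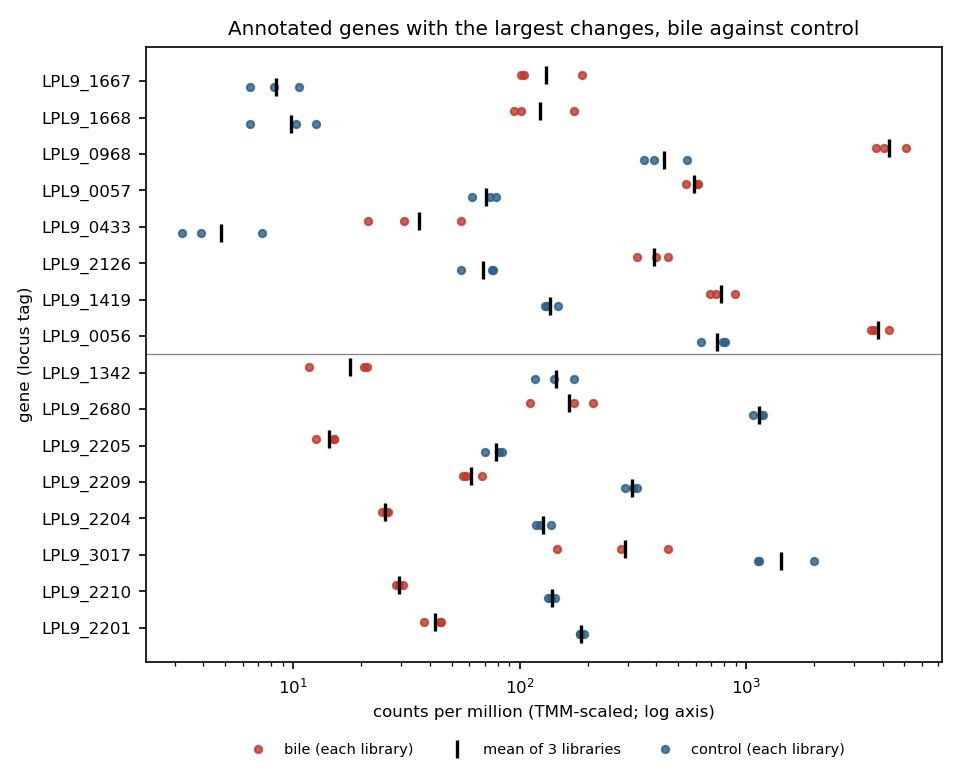
Expression in CPM (log axis, TMM-scaled) in each of the 3 bile and 3 control libraries for the 8 annotated genes with the largest rises (top) and the 8 with the largest falls (bottom); dots are libraries and vertical ticks are means. Genes were chosen to have groups that do not overlap, and LPL9_0968 had means of 432 CPM in the control and 4283 CPM with bile.

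Many genes of the translation machinery fell. Of 52 tested genes with the ribosomal structural term, 32 were lower, 5 were higher and 15 did not pass the test, with a median log2 fold change of -0.54 (camera adjusted p = 9.42e-05, but adjusted p = 0.673 with an estimated correlation). Adjusted over the list alone, 37 passed. The falls included LPL9_2588 (from 235 ± 2.65 to 82.1 ± 6.67 CPM, log2 fold change -1.52 ± 0.08 SE) and LPL9_1845 (-1.26 ± 0.07 SE). LPL9_1713, which also carries DNA-binding and peptidase terms, rose by 1.27 ± 0.17 SE on the log2 scale. A single chromosomal cluster at 2587318 to 2607560 held 19 of the 52 genes, of which 18 fell, with a median of -0.94. Of the 33 members elsewhere, 14 fell and 5 rose, with a median of -0.15. These cluster limits were set after a narrower definition, used first, had put 10 genes in the cluster and given a median of -0.34 for the other 42. Without the 19 genes, a comparison also made after the data were seen, the list was no longer called (camera adjusted p = 0.264).

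Aminoacyl-tRNA ligases, which charge tRNAs with amino acids, also moved down as a list. Of 22 tested genes, 16 fell, 1 rose and 5 did not pass the test, with a median log2 fold change of -0.42 (camera adjusted p = 0.00158, but adjusted p = 0.623 with an estimated correlation). Adjusted over the list alone, 17 passed. The neighbours LPL9_1664 and LPL9_1663 fell by log2 fold changes of -0.99 ± 0.09 and -0.87 ± 0.06 SE. The gene that rose, LPL9_2244 (0.81 ± 0.15 SE), carries both a valine-tRNA ligase and an NADP-binding term. Of 11 translation factor genes, 6 fell and 3 rose, but this list was not called (camera adjusted p = 0.371). Among those that fell was LPL9_2575, an initiation factor by its term, from 2942 ± 192 to 1493 ± 62 CPM.

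The third list called was metal transport, with 11 of 17 tested genes lower and 1 higher (median log2 fold change -0.35, camera adjusted p = 0.0182, but adjusted p = 0.623 with an estimated correlation). Formed instead by matching the fixed expression to GO term names, a choice made after the data were seen, the list held 131 tested genes and was not called (camera adjusted p = 0.801). Adjusted over the list of 17 genes, that is over the list alone, 12 passed. The list's name may describe it poorly. Of the 17 genes, 15 carry a ferrous iron transporter term, but 15 also carry a GTP-binding term, including 10 of the 11 that fell. GTP-binding proteins are a broad class that includes ribosome assembly and tRNA modification factors. The largest falls were LPL9_1512 (log2 fold change -1.24 ± 0.06 SE), LPL9_3039 (-1.07 ± 0.09 SE) and LPL9_1651 (-0.94 ± 0.08 SE).

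**Figure D2:**
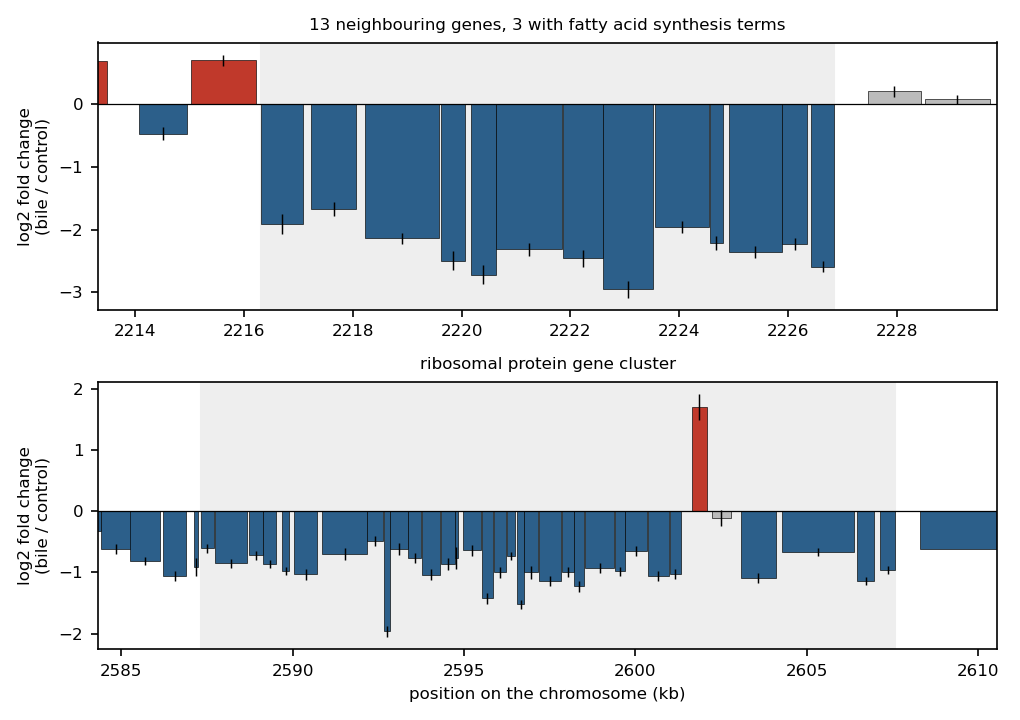
Log2 fold change, bile over control, of each tested gene (bar width is the gene's length; error bars are SE) against chromosome position in kb for 2 regions, with the region described shaded; red and blue bars are genes higher and lower at an adjusted p under 0.05 and grey bars are the others. The 13 genes from LPL9_2199 to LPL9_2211 lie between -2.95 and -1.67, and in the ribosomal protein cluster 18 of 19 list members are lower.

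Lists for the membrane and envelope were not called by camera, although single members changed strongly. Of 9 fatty acid synthesis genes, 5 fell and 1 rose (camera adjusted p = 0.264). The 3 members in the run of 13 fell most, and the 6 elsewhere had log2 fold changes between -0.31 and 0.34. The list holds only genes with a matching term, and 7 of the 13 genes in the run carry any term. The list's test therefore does not cover the rest of the run, whatever those genes encode. Among 16 peptidoglycan synthesis genes 9 fell and 2 rose (camera adjusted p = 0.196). The largest fall there was LPL9_2201, with a D-alanine-D-alanine ligase term, which lies in the run of 13. It was the only member to fall at least 2-fold and carries no process term, so its link to peptidoglycan is uncertain. Surface protein and pilus genes went the other way, with 11 of 21 higher and 4 lower (camera adjusted p = 0.31), led by LPL9_0056. Of 9 phospholipid genes 4 rose and 1 fell, including a diacylglycerol kinase by its term, LPL9_2233 (0.83 ± 0.13 SE). Isoprenoid genes were split, 6 higher and 7 lower of 18, with LPL9_0594 at -0.95 ± 0.12 SE. Polysaccharide and glycosyltransferase genes had 5 higher and 2 lower of 12, with LPL9_2394 at -0.61 ± 0.09 SE. The 2 tested cell wall hydrolase genes were both called higher, but the call of LPL9_1147, a lysozyme by its term (0.38 ± 0.14 SE, edgeR adjusted p = 0.0464), was lost in 10 of 17 alternative settings, including DESeq2 (adjusted p = 0.128). Adjusted p-values of LPL9_1147 ranged from 0.0365 with library totals to 0.185 without bile replicate 2.

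LPL9_0797, a malic enzyme by its term, rose 2.66-fold from 1990 ± 261 to 5295 ± 581 CPM (edgeR adjusted p = 1.84e-05, n = 3 each). In the pyruvate, acetate and citrate list as a whole 9 of 14 genes rose, 2 fell and 3 did not pass the test, with a median of 0.60, and the list was not called against the other genes (camera adjusted p = 0.264, adjusted p = 0.673 with an estimated correlation).

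Sugar and nucleotide genes showed no shared direction that camera called. Of 82 sugar phosphotransferase system genes, 22 rose, 10 fell and 50 did not pass the test (camera adjusted p = 0.354). Of 13 glycolysis genes 4 rose and 4 fell, the largest rise being LPL9_1543, a glucokinase by 1 of its terms (2.96-fold). Of 5 lactose and galactose genes 1 rose and 1 fell, the first being LPL9_0674, a beta-galactosidase by 1 of its terms (0.77 ± 0.13 SE). The purine list had 2 of 5 genes lower, including LPL9_0112, an adenylosuccinate synthase by its term (-0.51 ± 0.07 SE). The pyrimidine list had 2 of 7 lower and 2 higher, and its median (0.17) and mean (-0.06) differed in sign. It included LPL9_2651, a CTP synthase by its term, which fell from 4166 ± 311 to 2355 ± 132 CPM.

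Stress and transport genes gave mixed changes. Of 18 chaperone and protease genes 8 rose and 2 fell (camera adjusted p = 0.608), with the largest rise in LPL9_2329, a short gene of 282 bp with a protein folding term (3.67-fold, from 488 ± 194 to 1793 ± 449 CPM). Of 8 ATP synthase genes 4 rose and 1 fell, with LPL9_0830 at 0.75 ± 0.09 SE. Redox genes had 8 higher and 4 lower of 26, with LPL9_0264 at -1.06 ± 0.17 SE. DNA repair genes had 12 higher and 22 lower of 62, and regulatory phosphorelay genes 9 higher and 15 lower of 43. The largest change in both was LPL9_1341 (-1.96 ± 0.14 SE), which carries mismatch repair and phosphorelay terms. Of 3 drug transport genes 2 rose, LPL9_2702 by 0.82 ± 0.08 SE. Amino acid transport genes had 4 higher and 6 lower of 15, with LPL9_0888 at -1.34 ± 0.09 SE, and potassium, sodium and solute transport genes had 8 higher and 7 lower of 27. Peptidase and peptide transport genes had 32 higher and 23 lower of 95.

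A set of 3 adjacent plus-strand genes at 1261205 to 1265528, chosen after its values were seen, rose together at high abundance. LPL9_1281 and LPL9_1282 carry terms for ATP-driven transport across membranes and rose. LPL9_1281 had a log2 fold change of 2.02 ± 0.08 SE, and LPL9_1282 rose 3.79-fold from 602 ± 45.4 to 2281 ± 43.7 CPM (edgeR adjusted p = 5.49e-07, n = 3 each). LPL9_1280, upstream of them, has a DNA-binding term and a log2 fold change of 2.17 ± 0.08 SE. LPL9_1282 was also the largest change in the protein secretion list, where 4 of 14 genes rose and 5 fell, and the median (-0.27, also camera's direction) and mean (0.02, also fry's direction) differed in sign. Of 9 cell division genes 4 rose and 3 fell, led by LPL9_0968; the list's mean was 0.27 and its median -0.05, and the sign of the median depended on the scaling. Of 43 tested prophage, transposase and integrase genes 11 rose and 14 fell, with a median of -0.06 and a mean of 0.01, and 83 of the 142 rows in that list were at 0 in all libraries. Among the 24 tested lists that camera did not call, the smallest adjusted p was 0.196. Adjusted over the list alone, the number of genes passing changed in 6 of them: to 16 for surface proteins, 30 for the phosphotransferase system, 10 for translation factors, 12 for amino acid transport, 11 for redox genes and 9 for glycolysis.

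**Figure D3:**
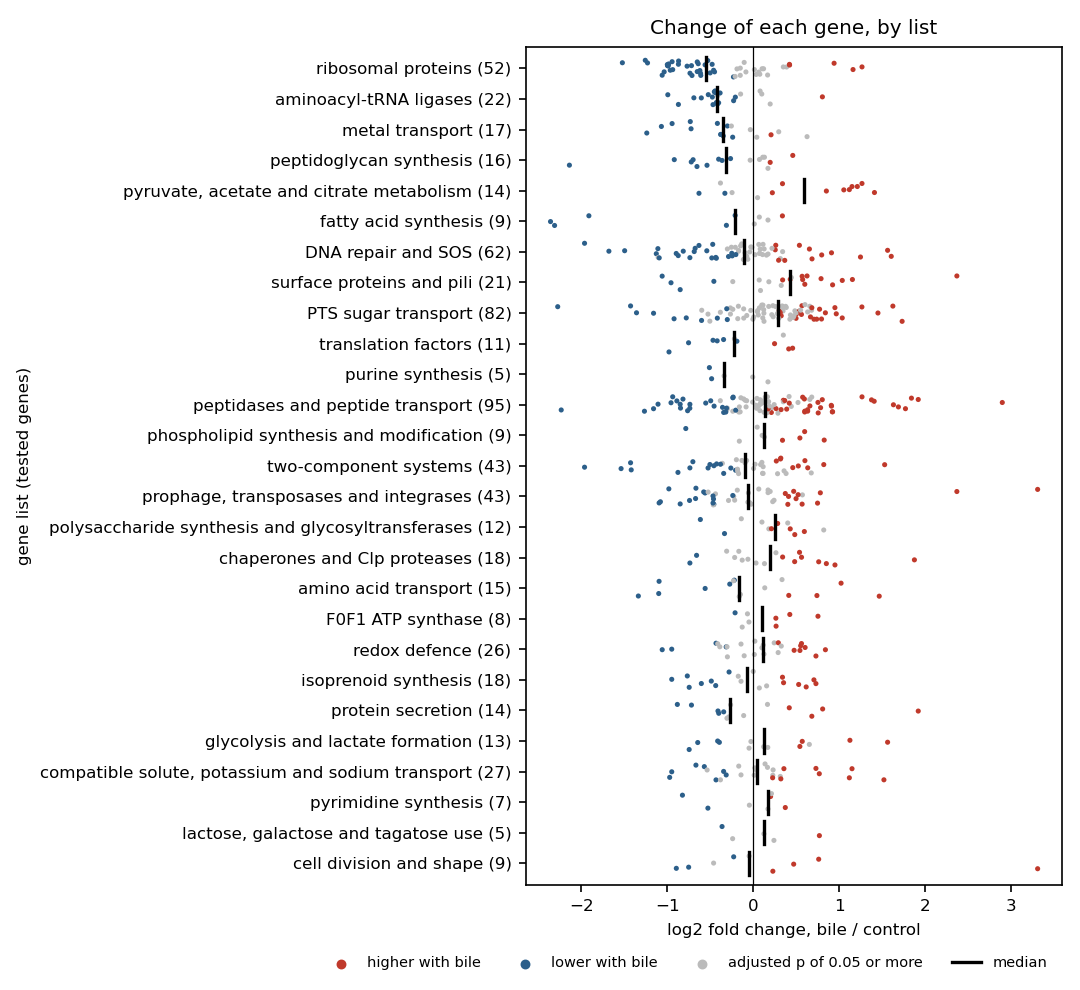
Log2 fold change, bile over control, of every tested gene in the 27 lists tested by camera, ordered by camera's adjusted p with the smallest at the top and the number of tested genes in parentheses; red and blue dots are genes higher and lower at an adjusted p under 0.05, grey dots are the others and black bars are medians. Medians of the 3 called lists lie at -0.54, -0.42 and -0.35.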

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

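A pair of list alternatives, the fixed expressions matched to GO term names and the ribosomal list without its cluster, were chosen after the data were seen; the others had been planned. The main fit called 1437 genes, more than any alternative. Between 1294 and 1436 were called in 11 alternatives of test, scaling, filter, block and unit. When each library was left out in turn, between 1222 and 1406 were called. Of the genes called in the alternatives, between 1207 and 1409 were shared with the 1437. Rises made up 52.6% of the calls and between 48.6% and 58.8% across alternatives, and no scaling moved the median of all genes by as much as 0.1 on the log2 scale. At least 2-fold changes numbered 306, with a range of 286 to 320. With the replicate number as a block 1348 genes were called. Same-numbered libraries did not deviate together (correlations of -0.01, 0.08 and -0.03), and not every sample correlated best with its own number. No pairing by number was therefore seen, but 3 libraries per group are too few to exclude one. None of the 799 alternative values of the 47 named genes changed sign, and 789 kept their side of the threshold. The other 10 belonged to LPL9_1147. The named genes had been picked past the threshold by size of change in these same libraries, so this says little about the other genes called. The same 3 lists were called with each library left out, under the block, with RLE factors, library totals or the stricter filter, and on log2(FPKM + 1). Camera with an estimated correlation called 0 lists (0 at an unadjusted p under 0.05), fry, which does not compare a list with other genes, called 24 of 27, the fixed expressions called 1, the aminoacyl-tRNA ligases, and not metal transport (adjusted p = 0.801), with no ribosomal list tested, and removal of the ribosomal cluster left 2. Depth limited 142 genes with counts, of at most 64 counts over all libraries, which were not tested.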

Other observations

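The splits of the libraries, the tests on rows at 0, the ribosomal tests that use genes linked within 5000 bp and the runs of neighbouring genes were chosen, or their criteria written, after the results were seen. Neighbouring genes moved together beyond the runs already described. In all, 80 of the genes changed at least 2-fold lay in 19 runs of 3 or more, against at most 18 genes in 10000 shuffles of position. Those shuffles also treat neighbouring genes as independent. A run of 5 minus-strand genes, LPL9_2152 to LPL9_2156 at 2160884 to 2166645, rose by log2 fold changes between 1.38 and 1.96, and LPL9_2152 and LPL9_2153 carry peptide transport terms. At 1706181 to 1711174, LPL9_1710 and LPL9_1712, both with unfolded protein binding terms, rose by 0.56 and 0.85 on the log2 scale beside LPL9_1713, which rose by 1.27.

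Among rows other than numbered genes, 5 of 14 tested small RNA rows rose and 6 fell, and 0 of 14 tested transfer RNA rows rose and 4 fell. A scan of 624 GO terms called 12, all lower with bile, including translation (83 genes, 54 lower and 7 higher, camera adjusted p = 8.53e-06), RNA binding (60 lower and 15 higher of 109) and structure-specific DNA binding (14 lower and 2 higher of 22). The 12 also held the terms behind the ribosomal list (52 genes) and the aminoacyl-tRNA ligase list (22 genes). The scan is therefore not separate evidence for these lists. Transition metal ion transport, with 17 genes as in the metal transport list, was not called (camera adjusted p = 0.06). Over the scan, the smallest adjusted p with an estimated correlation was 0.846. Terms whose estimate lay below the preset 0.01 also lost their call, such as ligase activity (-0.007, camera adjusted p = 0.0064 with the preset). The large p-values of that setting, here and for the lists, therefore do not by themselves show that correlation between genes accounts for the falls. For translation and the ribosomal structural term the estimates were 0.149 and 0.249, above the preset. There, correlation may have contributed to the lost call.

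The number of genes called cannot be set against chance by regrouping: 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real split called 1437 genes and the highest of the other splits 0, and 1 split gave as many as the real one, the real split itself.

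The ribosomal protein list's median of -0.54 lay below the 2.5th percentile of 10000 random lists matched on mean expression (-0.28) or on length (-0.046), which argues against either trend as the whole cause, although random lists treat genes as independent and the list's estimated correlation was 0.249. That result rests on the cluster: the 33 members outside it had a median of -0.15 (bootstrap 95% interval -0.46 to 0.07), against 2.5th percentiles of -0.36 for lists matched on expression and -0.14 on length, so for these members neither trend is excluded. Whether the fall belongs to the cluster alone was first tested with a stretch of 10 neighbouring members, and a median below -0.3 for the rest, set beforehand, was to count against this; the other 42 had -0.34 (-0.58 to -0.08), which met the bound but not by more than its spread. That stretch had left 9 genes of the cluster outside, so genes were then linked within 5000 bp, which gave the 33 above and decides neither way. Slower growth with bile may also lower such genes; growth rates were not analysed here and that hypothesis was not tested.

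Stretches of adjacent rows had 0 counts in all libraries, the longest with 55 rows against at most 9 in 10000 shuffles. Reads shared between identical copies are a candidate explanation where lengths recur: 97.6% of 41 numbered zero rows with a DNA integration term had the exact length of another zero row (upper bound of the central 95% of random sets 56.1%), as did 84.8% of the 33 rows from LPL9_1072 to LPL9_1113, where an ordered stretch of 7 gene lengths occurs in repeat. Equal length is not equal sequence, which was not compared here. In the stretch of 55 rows from LPL9_1199 to LPL9_1261 (1202300 to 1247937) the share was 45.3% of its 53 numbered rows, within the range of random sets (up to 54.7%), which argues against copies as the cause of the whole stretch. That region had 0 of 21393007 counts, which allows up to 3; genes with no transcription in this medium and DNA missing from the cultured cells cannot be told apart from counts of RNA.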
